A study of Arabidopsis thaliana with 94 samples.

How the data were processed

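The series measured Arabidopsis seedlings by ChIP-seq (69 samples), GRO-seq (4), RNA-seq (16) and sequencing of small RNAs bound to nuclear AGO1 (5). Only the RNA-seq tables and the small RNA files were used here. Samples were grouped by the titles in the labels, and the groups were WT and ago1-36 with MeJA or buffer (3 RNA-seq samples each), untreated WT and ago1-36 (2 each), and the small RNA libraries of untreated WT (2), WT with buffer, WT with MeJA and coi1 with MeJA (1 each). The labels do not say that samples of a group came from separate plantings, so the deposited p-values may measure technical spread only. Per the labels' protocols, RNA-seq libraries were made from total RNA of whole seedlings with 1 of 2 library kits, without saying which samples had which, and small RNAs were extracted from AGO1 immunoprecipitates of isolated nuclei.

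Each of the 3 RNA-seq tables has the layout Cuffdiff writes, per the file headers, and Cuffdiff, Bowtie, HOMER and MACS2 are named without versions or roles in the submitters' processing notes, with TAIR10 as the genome build. The deposited FPKM values (fragments per kilobase of transcript, scaled to library size) are 1 value per group, made by the authors from all replicates of the group and normalized within each table. The deposited log2 fold changes equal the log2 ratio of the group FPKM values. The deposited score in each table is the test statistic, and the deposited p-value and q-value of each gene are the authors' own test. The settings of alignment, counting and testing are not given in the sources used here, nor is how reads shared by near-identical genes were assigned or whether strand was used. Each table holds 33279 genes, of which 19415 (WT with MeJA), 19509 (ago1-36 with MeJA) and 19727 (untreated) had the test status OK. The smallest deposited p-value is 5e-05. No test of replicates was possible on pooled values, so the authors' q at 0.05 decided which genes rose or fell. The deposited small RNA files give a count of reads for each distinct sequence of 18 to 28 nt, with no normalization by the authors (19 to 28 nt in untreated WT 2). These totals are of that length window and may not be the whole library.

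Gene lists, comparisons, tests and most alternatives were fixed before the data were examined. Each of 19 lists (285 loci) was tested per comparison and direction with a two-sided Fisher's exact test of called against other genes among all tested genes, with Benjamini-Hochberg adjustment over the 19 lists. These tests treat genes as independent, and members of a pathway are not. Counts adjusted over the list alone applied the same adjustment to the deposited p-values of the tested members. The difference of the MeJA response was the deposited log2 fold change in ago1-36 minus that in WT, for genes chosen by a call in WT, in ago1-36, in both or in either. It was left without a test, because the deposited statistic did not give the deposited p as a normal deviate. Ratios across tables used log2(FPKM + 1). Overlaps were tested with Fisher's exact test over genes tested in both tables, adjusted over the 4 direction pairs. Gene symbols came from a RefSeq gene table (assembly TAIR10.1, used for names only), which held 32813 of the 33279 loci, and list members carry the symbol of the list. Coordinates are the locus intervals of the files, with starts counted from 1. At least 1 end equalled that of the RefSeq gene for 16467 of 32813 genes, so the intervals need not be the bounds of the gene itself.

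Genes named in the text followed a rule fixed along with those lists. AGO1 and COI1 came first, then the 5 largest rises and 5 largest falls among called genes with at least 5 FPKM in the higher group, and up to 4 called members and 1 other member per list. For the difference of the response, the 5 furthest on each side were named. Genes listed at 0 in 1 group are given apart, with no fold. For small RNAs, the rule took the 10 families with the highest mean RPM over the WT libraries and the 4 largest and 4 smallest ratios per comparison among families with at least 100 reads in 1 library.

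No reference genome was used here, so small RNAs were not mapped. The planned shares by genomic source, and the small RNAs at MeJA-responsive and AGO1-dependent genes, are therefore not analysed here. RPM is the read count scaled to the total of deposited reads of a library, where reads matching the genome had been planned. MicroRNA and trans-acting siRNA names rest on exact matches to 46 and 4 mature sequences written down from general knowledge after the files were opened, not on a database. The TAS2 sequence had no reads in any library and TAS4 was not looked up. Ratios of 2 libraries carry exact conditional binomial 95% intervals, and shares carry exact Clopper-Pearson 95% intervals. Depth ran from 6686453 to 15735450 reads.

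The list test, the adjustment and the ratio interval were tested on simulated data. With the 19415 genes of the WT table, 200 simulated lists of 15 genes unrelated to the calls passed in 1.0% of draws at an unadjusted p under 0.05, and 200 enriched lists passed in 100% of draws. The enriched lists had a calling chance set far above the background, so this gives no power for lists with weaker enrichment. Of the intervals of 500 simulated ratios, with counting error only, 95% held the true ratio. Alternatives covered the q threshold (0.01), a 2-fold minimum, an FPKM minimum of 1, pseudocounts of 1 and 0.1, median-of-ratios scaling, a list background of at least 5 FPKM, the choice of genes for the difference, and for small RNAs the total of 20 to 22 nt reads, a minimum of 20 reads and median-of-ratios scaling. Counting the form lacking the last base together with the mature sequence was added after the data were seen, as was the grouping of genes into families by symbol. Work was done with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.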

Results

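Messenger RNA and AGO1-bound small RNA were measured in 10-day-old Arabidopsis thaliana seedlings. Methyl jasmonate (MeJA), an ester of the wound and defence hormone jasmonic acid (JA), was given at 50 μM for 1 h, and plants given buffer served as its controls. The mutant ago1-36 carries a lesion in ARGONAUTE1 (AGO1), the main protein through which plant microRNAs act, and coi1 lacks the F-box protein COI1, part of the jasmonate receptor. RNA-seq covered wild type (WT) with MeJA, WT with buffer, ago1-36 with MeJA and ago1-36 with buffer, 3 samples in each, and untreated WT and untreated ago1-36, 2 samples in each. Small RNAs bound to nuclear AGO1 were sequenced in 2 untreated WT samples and in 1 sample each of WT with buffer, WT with MeJA and coi1 with MeJA. The RNA-seq values were 1 FPKM value per group with the authors' fold changes, p-values and q-values, so the depth of these libraries is unknown and no spread between replicates could be given. The small RNA libraries held 15038252 and 6686453 reads (untreated WT 1 and 2), 15735450 (WT with buffer), 13746223 (WT with MeJA) and 15275066 (coi1 with MeJA). The 69 ChIP-seq and 4 GRO-seq samples of the series are not analysed here.

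The comparison of MeJA with buffer in WT asked which genes respond to the hormone within 1 h. Genes of the jasmonate pathway itself rose, from its repressors to the enzymes that make and break down the hormone. AGO1 (AT1G48410, deposited locus interval chromosome 1, 17885633 to 17892596 in TAIR10) stood at 76.3 FPKM with buffer and 73.0 with MeJA in the authors' deposited table (q = 1.00), and COI1 (AT2G39940, deposited locus interval chromosome 2, 16666023 to 16675748) at 20.2 and 16.4 (q = 1.00). These intervals need not be the bounds of the genes. Of 19415 genes tested there, 1108 rose and 395 fell at a q under 0.05. Of these, 798 of the raised and 213 of the lowered genes changed at least 2-fold. The smallest q the table holds is 0.00116, shared by 836 genes, so most of the genes named below have that value.

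JAZ repressors, the proteins that hold jasmonate transcription factors inactive, rose in 10 of 12 tested members and fell in none (two-sided Fisher's exact test against all tested genes, adjusted p = 1.33e-10). The count adjusted over the list alone was also 10. In the authors' deposited table JAZ8 went from 2.14 to 107 FPKM (50.3-fold), JAZ7 from 2.73 to 121 (44.2-fold), JAZ10 from 14.6 to 401 (27.5-fold) and JAZ5 from 4.14 to 94.1 (22.7-fold), each at q = 0.00116. JAZ11 did not pass there, at 11.6 and 12.4 FPKM. JA biosynthesis genes rose in 13 of 15 members (adjusted p = 1.14e-13, Fisher's exact test; 14 when adjusted over the list alone). The authors' deposited table lists the lipoxygenases LOX4 and LOX3 at 14.5-fold and 13.7-fold higher with MeJA, the allene oxide cyclase AOC1 at 71.3 against 765 FPKM and the allene oxide synthase AOS at 79.5 against 797. KAT2, a thiolase of peroxisomal beta-oxidation, stood at 160 and 159 FPKM in that table. All 9 tested genes of JA catabolism rose (adjusted p = 5.92e-11, exact test; 9 when adjusted over the list alone). Among them, the hormone-oxidising enzymes CYP94B1, JOX4, JOX3 and CYP94B3 were 34.6-fold, 27.8-fold, 26.4-fold and 15.4-fold higher in the authors' deposited table.

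JA transcription factors rose in 10 of 13 members (adjusted p = 4.09e-10, Fisher's exact test; 11 when adjusted over the list alone). The authors' deposited table places ERF109 39.6-fold higher (q = 0.0431), ANAC019 16.1-fold, JAM1 7.21-fold and MYC2, the master regulator of the pathway, 6.96-fold, from 27.8 to 193 FPKM; MYC3 did not pass, at a log2 fold change of 0.59 (q = 0.0843). JA output genes rose in 6 of 9 members (adjusted p = 5.86e-06, exact test; 7 when adjusted over the list alone), led in that deposited table by the vegetative storage proteins VSP1 (27.0-fold) and VSP2 (17.4-fold) and the tyrosine aminotransferase TAT3 (17.8-fold), with CORI3 at 4.64-fold. PR4, a chitin-binding defence protein, did not pass, at 129 and 142 FPKM in the authors' deposited table. Early stress and touch genes rose in 9 of 18 members (adjusted p = 5.41e-07, exact test; 9 when adjusted over the list alone). Of these, WRKY40 was 9.16-fold higher in the authors' deposited table, ZAT10 4.97-fold, WRKY18 4.59-fold and CML38 4.08-fold, while TCH3 did not pass, at 422 and 460 FPKM.

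Glucosinolates, the sulfur-rich defence compounds of the cabbage family, were represented by lists of their indole and aliphatic branches. In WT, 9 of 11 indole glucosinolate and tryptophan genes rose (adjusted p = 1.17e-09, Fisher's exact test; 9 when adjusted over the list alone), including the regulator MYB34, 6.26-fold, and CYP79B3, 6.01-fold in the authors' deposited table. Of the aliphatic branch 7 of 10 rose (exact test, adjusted p = 5.41e-07; 9 when adjusted over the list alone), including CYP79F1 at 2.88-fold and SOT17 at 2.46-fold in that deposited table. Flavonoid and anthocyanin genes rose in 5 of 12 members (adjusted p = 0.000716, exact test; 5 when adjusted over the list alone), PAP1 at 5.59-fold and UF3GT at 4.52-fold in the authors' deposited table. Cold response genes rose in 3 of 10 (adjusted p = 0.0312, exact test; 3 when adjusted over the list alone), with the neighbouring, closely similar KIN1 and KIN2 at 2.02-fold and 1.79-fold in that deposited table.

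The remaining lists did not pass in WT. SA and immunity genes gave 1 rise and 1 fall of 15, auxin response genes 1 rise and 2 falls of 13, and microRNA targets 5 rises and 2 falls of 55; adjusted over the list alone the counts were 1 and 1, 2 and 2, and 5 and 2. The authors' deposited table lists the salicylate transporter EDS5 at 4.09-fold higher, the receptor kinase FRK1 at 2.71-fold lower, the auxin-conjugating enzyme GH3.3 at 2.75-fold higher and GH3.5 at 1.66-fold lower. SPL13B and SPL13A, near-identical copies that can share reads, were at 2.61-fold and 2.58-fold higher there. None of the 19 photosynthesis, 18 small RNA machinery, 9 root marker, 3 trans-acting siRNA target or 6 reference genes passed, and adjusted over the list alone 1 trans-acting siRNA target did. The only seed storage gene tested, SESA1, rose from 0.727 to 16.6 FPKM in the authors' deposited table (list adjusted p = 0.0986, exact test; 1 when adjusted over the list alone).

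Over all genes with at least 5 FPKM in the higher group, the largest rises in the authors' deposited table for WT were those of the terpene synthase TPS04 (AT1G61120, 0.241 to 24.3 FPKM, 101-fold), AT3G22275 (0.750 to 54.9), MAPKKK21 (0.364 to 19.7), the farnesoic acid methyltransferase FAMT (9.17 to 468) and JAZ8. AT5G63270 was listed at 0 with buffer and at 6.21 FPKM with MeJA in that deposited table. The largest falls there were those of the fatty acid elongase KCS12 (13.1 to 1.98 FPKM, 6.61-fold), the nitrate transporter NRT2:1 (10.2 to 1.98, 5.15-fold), AT5G40590 (4.48-fold), AT3G62550 (4.18-fold) and AT5G41900 (4.09-fold).

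The same comparison within ago1-36 asked whether the mutant still responds. The jasmonate lists held more raised genes than the background of tested genes there as well. AGO1 stood at 7.10 FPKM with buffer and 6.49 with MeJA in the authors' deposited table for ago1-36 (q = 0.999), and COI1 at 16.6 and 15.6 (q = 0.999). Of 19509 genes tested in that table, 1117 rose and 405 fell, 537 and 133 of them at least 2-fold. JAZ repressors rose in 11 of 12 members (adjusted p = 2.24e-12, two-sided Fisher's exact test; 11 when adjusted over the list alone), JA biosynthesis genes in 14 of 15 (1.02e-15; 14) and JA catabolism genes in 9 of 9 (4.06e-11; 9). In the authors' deposited table JAZ7 went from 9.71 to 66.4 FPKM (6.84-fold), JAZ8 from 26.9 to 153 (5.67-fold), JAZ10 from 122 to 612 (5.00-fold) and JAZ2 from 71.3 to 254 (3.57-fold), each at q = 0.00115, while JAZ11 stood at 10.6 and 10.5. That deposited table has the methyltransferase JMT at 1.35 and 5.54 FPKM, and as higher DAD1 at 2.88-fold, OPR3 at 2.85-fold and AOS at 2.80-fold, CYP94B1 at 12.8-fold, JOX4 at 6.80-fold, JOX3 at 6.05-fold and CYP94B3 at 4.39-fold. KAT2 did not pass there, with a log2 fold change of 0.02.

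JA transcription factors rose in 7 of 13 members in ago1-36 (adjusted p = 9.52e-06, Fisher's exact test; 9 when adjusted over the list alone), JA output genes in 4 of 9 (0.00254; 6) and early stress and touch genes in 7 of 18 (0.000114; 7). The authors' deposited table has ERF109 at 5.22-fold, JAM1 at 3.23-fold, MYC2 at 2.99-fold (54.4 to 163 FPKM) and RGL3 at 2.79-fold higher, and MYC3 at 30.3 and 41.5 FPKM (q = 0.0677). TAT3 was 5.87-fold, VSP2 3.89-fold, CORI3 2.74-fold and VSP1 2.00-fold higher in that deposited table, and PR4 stood at 274 and 318 FPKM without passing. WRKY40 was 2.59-fold, ZAT6 1.99-fold, CML38 1.95-fold and WRKY18 1.92-fold higher in the authors' deposited table, with TCH3 at 541 and 557 FPKM. Indole glucosinolate and tryptophan genes rose in 9 of 11 members (1.51e-09, exact test; adjusted over the list alone, 9 rose and 1 fell), aliphatic glucosinolate genes in 5 of 9 (0.000172; 5) and cold response genes in 3 of 10 (0.0350; 3).

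Flavonoid and anthocyanin genes did not pass as a list in ago1-36, with 1 rise of 10 (adjusted p = 0.705, exact test; 1 when adjusted over the list alone), that of PAP1 at 3.90-fold in the authors' deposited table. SA and immunity genes gave 1 rise and 2 falls of 18, auxin response genes 1 and 1 of 12 and microRNA targets 7 and 1 of 58; adjusted over the list alone the counts were 1 and 4, 1 and 1, and 7 and 1. WRKY54 and WRKY70, regulators of salicylate defence, were 2.18-fold and 1.48-fold lower in that deposited table, and the flowering repressors SMZ and TOE3, both targets of miR172, were 2.68-fold and 2.40-fold higher. SESA1 rose 3.85-fold in the authors' deposited table. None of the 19 photosynthesis, 20 small RNA machinery, 8 root marker, 3 trans-acting siRNA target or 6 reference genes passed, and adjusted over the list alone 1 trans-acting siRNA target did. The largest rises over all genes with at least 5 FPKM were AT1G12540 (56.8-fold, q = 0.0359), AT5G04120 (39.3-fold), AT3G22250 (33.2-fold), AT3G44870 (28.7-fold) and AT4G22214 (21.4-fold) in the authors' deposited table. The largest falls there were USPL1 (4.04-fold), the brassinosteroid-induced factor BEE3 (3.62-fold), AT5G40590 (3.38-fold), BAT1 (9.39 to 2.85 FPKM) and the cambium regulator WOX4 (3.25-fold). With a pseudocount of 1 the log2 fold change of AT1G12540 was 2.59, against 4.45 for AT3G22250. The first rank of AT1G12540 among the rises therefore rests on a buffer value near 0.

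**Figure D1:**
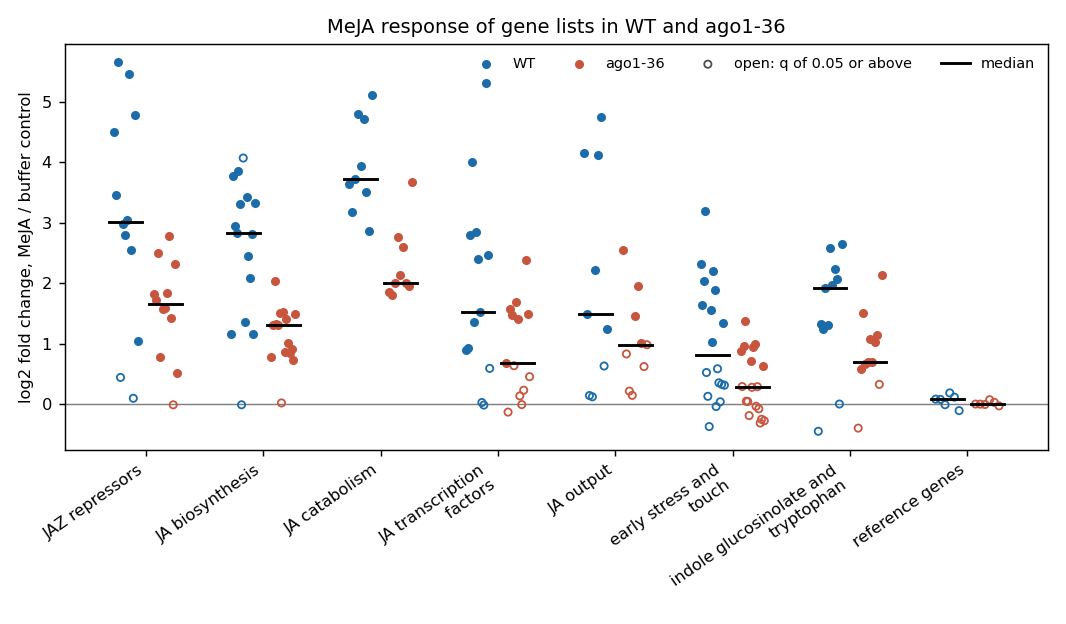
Each point is a tested member of a gene list, placed on the vertical axis by its log2 fold change of MeJA over buffer control in the authors' deposited tables, blue for WT and red for ago1-36; filled points have a q under 0.05 and black bars are medians. The medians of the JAZ repressors are 3.01 in WT and 1.65 in ago1-36, those of JA catabolism 3.72 and 2.01, and the reference genes sit near 0 in both.

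Whether the response had the same size in both genotypes was described without a test, because the deposited statistics, read as normal deviates, do not return the deposited p-values (within 0.01 for 10.5% and 9.91% of genes). Jasmonate genes had smaller fold changes in ago1-36. Of the 12 JAZ repressors 11 had a smaller log2 fold change there, with a median difference (ago1-36 minus WT) of -1.31. The same held for 14 of 15 JA biosynthesis genes (median -1.49), 9 of 9 JA catabolism genes (-1.71), 12 of 13 JA transcription factors (-0.99), 7 of 9 JA output genes (-0.66) and 16 of 18 early stress and touch genes (-0.65). Medians over the reference genes (-0.08), photosynthesis genes (0.01), microRNA targets (0.04) and all 19000 genes tested in both tables (-0.01) lay near 0.

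Genes that rose in WT had a median difference of -0.46, with 997 of 1105 below 0, and those that rose in ago1-36 had one of -0.32, with 843 of 1113 below 0. For genes that fell, the direction turned with the choice of genes: the median was 0.33 over those that fell in WT and -0.04 over those that fell in ago1-36. Calls were shared to a large extent: 873 genes rose in both genotypes, against 62.8 expected for independent lists, and 201 fell in both, against 7.72 (Fisher's exact test, odds ratios 320 and 112). Rises without a call in the other genotype numbered 235 in WT and 243 in ago1-36. EXPA1, an expansin that loosens cell walls, was the only gene with calls in opposite directions: the authors' deposited tables list it at 78.4 FPKM with buffer and 41.8 with MeJA in WT, and at 35.8 and 52.6 in ago1-36 (q = 0.00116 and 0.0171). It was named after its values were seen.

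Among genes called in at least 1 genotype with 5 FPKM or more, the differences furthest below 0 in the authors' deposited tables were those of TPS04 (-4.54; 0.241 to 24.3 FPKM in WT, 4.42 to 19.2 in ago1-36), MYB113 (-4.45), AT1G73325 (-4.34), HSD4 (-3.87) and MYB21 (-3.77). Of these, MYB113, AT1G73325, HSD4 and MYB21 were not called in WT. Their WT buffer values lay near 0, at 0.0514, 0.211, 0.0350 and 0.0333 FPKM, so the sizes of these differences are uncertain. The FPKM minimum applied to the highest group only. HSD4 was called lower in ago1-36 (5.07 to 2.01 FPKM) and stood at 0.0350 and 0.203 in WT, so its difference is not a smaller rise. The differences furthest above 0 there were those of AT1G53890 (2.48), AIG1 (1.93), AT4G37850 (1.87), KCS12 (1.55) and AT3G29000 (3.37 to 1.01 FPKM in WT, 9.82 to 8.28 in ago1-36). AT1G53890, AT4G37850 and AT3G29000 were not called in ago1-36, and AIG1 was not called in WT. In ago1-36 with buffer, AT1G53890 and AT4G37850 also lay near 0, at 0.155 and 0.0234 FPKM.

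Levels set across the MeJA tables, which were normalized separately, showed where the genotypes differed. With buffer, JAZ repressors were higher in ago1-36 than in WT by a median of 1.28 on the log2(FPKM + 1) scale, and with MeJA they stood at -0.19. JA biosynthesis genes were at 1.46 with buffer and 0.02 with MeJA, JA catabolism genes at 1.42 and -0.27, and early stress and touch genes at 1.18 and 0.42. JA output genes were at 0.44 with buffer (5 of 9 above WT) and -0.18 with MeJA, but at 2.42 in untreated plants (8 of 9). Over the 873 genes that rose in both genotypes the medians were 0.49 and 0.10, and over all genes tested in both they were 0.05 and 0.04. JAZ10 shows the higher buffer level in the authors' deposited tables, with 14.6 FPKM in WT and 122 in ago1-36. With MeJA, at 401 and 612, it stayed above WT, as did 5 of the 12 JAZ repressors in all.

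**Figure D2:**
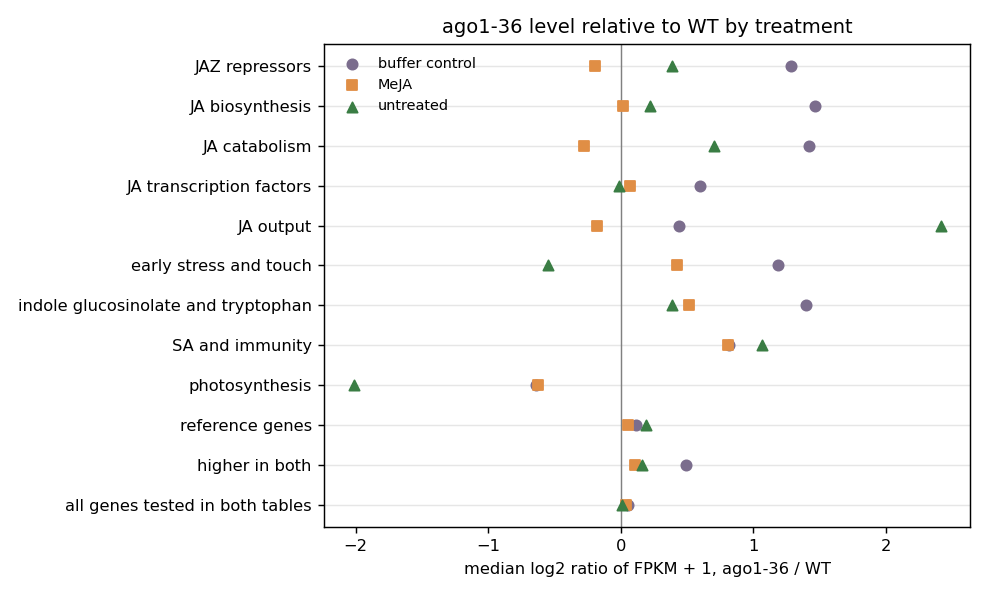
The horizontal axis is the median over a gene set of the log2 ratio of FPKM + 1 between ago1-36 and WT, with circles for buffer controls, squares for MeJA and triangles for untreated plants; the tables behind the treatments were normalized separately. JAZ repressors lie at 1.28, -0.19 and 0.39, and all genes tested in both MeJA tables at 0.05, 0.04 and 0.01.

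The comparison of untreated ago1-36 with untreated WT asked which genes depend on AGO1 without a stimulus. The photosynthesis, auxin response and cold response lists held more lowered genes than the background of tested genes, and the salicylate immunity, jasmonate output and microRNA target lists held more raised ones. Other members of each list did not pass, except that 2 cold response genes were higher and 5 microRNA targets lower. AGO1 itself fell from 53.3 FPKM in WT to 9.78 in ago1-36 in the authors' deposited table (5.45-fold, q = 0.00100). Of 19727 genes tested in that table, 1230 were higher and 1265 lower in ago1-36, 1095 and 1159 of them at least 2-fold. The smallest q there is 0.00100, shared by 982 genes. Each of these groups was made from 2 samples.

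Photosynthesis genes were lower in ago1-36 in 14 of 19 members (adjusted p = 3.03e-12, two-sided Fisher's exact test; 16 when adjusted over the list alone). In the authors' deposited table the light-harvesting genes LHCB2.1 and LHCB2.2, near-identical copies, fell 8.45-fold and 8.25-fold, LHCB3 6.77-fold (3281 to 485 FPKM) and LHCB4.2 6.22-fold, while RBCS1A, the Rubisco small subunit, did not pass, at 23232 and 17432 FPKM. Auxin response genes were lower in 8 of 13 (adjusted p = 2.56e-06, exact test; 9 when adjusted over the list alone), with the auxin-inducible repressors IAA29 17.4-fold and IAA3 8.47-fold lower in that deposited table. Cold response genes were lower in 6 of 13 (adjusted p = 0.000505, exact test; 8 when adjusted over the list alone) and higher in 2. There the authors' deposited table lists the regulator CBF1 at 15.9 in WT and 1.27 FPKM in ago1-36, GOLS3 at 5.71 and 0.447, and COR15B, in the other direction, at 27.7 and 108. Early stress and touch genes were lower in 6 of 18 and higher in 1 (adjusted p = 0.00310, exact test; 8 lower when adjusted over the list alone), with ERF105 3.33-fold, TCH4 2.98-fold, ERF6 2.89-fold and ERF5 2.88-fold lower in that deposited table. Root markers were lower in 4 of 10 (adjusted p = 0.00982, exact test; 8 when adjusted over the list alone): CASP2 by 4.13-fold, PRP3 by 3.97-fold, LRX1 by 3.70-fold and CASP1 by 3.24-fold in the authors' deposited table. These median differences were smaller, near 0 or of the other sign between the buffer controls, across tables normalized separately and perhaps made with different library kits, which the labels do not assign to samples. RNA-seq sample titles of the MeJA and buffer groups also end in mate1, and those of the untreated groups do not, so the read format may differ too. Over genes tested in both MeJA tables the median log2(FPKM + 1) ratio of ago1-36 to WT was -2.01 untreated and -0.64 with buffer for photosynthesis, -1.42 and 0.09 for auxin response, -0.72 and 0.45 for cold response, -0.55 and 1.18 for early stress and touch, and -1.30 and -0.08 for root markers.

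SA and immunity genes were higher in ago1-36 in 10 of 18 members (adjusted p = 2.25e-07, Fisher's exact test; 13 when adjusted over the list alone). The pathogenesis-related PR1 stood at 95.9 FPKM in WT and 765 in ago1-36 (7.98-fold), FMO1 at 1.19 and 8.66, PBS3 at 2.35 and 14.0, and FRK1 at 8.95 and 47.8 in the authors' deposited table; WRKY53 did not pass. JA output genes were higher in 8 of 9 (adjusted p = 3.61e-08, exact test; 8 when adjusted over the list alone), including the defensins PDF1.2, PDF1.2c and PDF1.2b at 8.84-fold, 7.32-fold and 6.60-fold and VSP1 at 7.16-fold in that deposited table. The defensin genes are close copies, and VSP1 and VSP2 are as well, so reads may be split between them. JA catabolism genes went both ways, with 4 of 9 higher (adjusted p = 0.00699, exact test) and 3 lower (adjusted p = 0.0522), and 5 and 3 when adjusted over the list alone. Among them JOX4 was 8.05-fold and JOX3 5.57-fold higher, and CYP94B3 8.96-fold and CYP94B1 4.96-fold lower, in the authors' deposited table.

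MicroRNA targets were higher in 15 of 58 members (adjusted p = 1.14e-05, Fisher's exact test; 23 when adjusted over the list alone) and lower in 5. The copper/zinc superoxide dismutases CSD1 and CSD2, targets of miR398, stood at 98.6 and 127 FPKM in WT and at 616 and 739 in ago1-36 in the authors' deposited table. The AP2-type factors SNZ and TOE1, targets of miR172, went the other way there, 6.73-fold and 4.34-fold lower, and the sulfate transporter SULTR2;1 did not pass, at 89.5 and 107 FPKM. Of the 19 small RNA machinery genes tested, AGO2 rose from 7.33 to 30.4 FPKM (4.15-fold) and RDR1 2.37-fold, AGO1 fell, and the others did not pass, SE standing at 29.6 and 31.4 FPKM in the authors' deposited table (list adjusted p = 0.635, exact test; 2 higher and 1 lower when adjusted over the list alone). AGO2 is itself on the microRNA target list. None of the trans-acting siRNA targets ARF2, ARF3 and ARF4 passed, and none did when adjusted over the list alone, with ARF2 at 79.9 and 68.9 FPKM in that deposited table.

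JAZ repressors were higher in untreated ago1-36 in 2 of 12 (adjusted p = 0.403, exact test; 2 when adjusted over the list alone), JAZ9 by 2.01-fold and JAZ6 by 1.91-fold in the authors' deposited table. JA biosynthesis genes were higher in 3 of 14 and lower in 1, JA transcription factors higher in 3 and lower in 2 of 13, and neither list passed (adjusted over the list alone, 4 and 1, and 4 and 2). LOX2 stood at 243 FPKM in WT and 1018 in ago1-36 and AOS at 69.9 and 24.1 in that deposited table. Indole glucosinolate and tryptophan genes (3 higher and 1 lower of 10), aliphatic glucosinolate genes (2 lower of 10), flavonoid genes (1 higher of 9) and seed storage genes (2 lower of 4) did not pass; adjusted over the list alone the counts were 3 and 2, 1 higher and 2 lower, 1 higher, and 2 lower. None of the 6 reference genes passed, or did when adjusted over the list alone. UBQ10 stood at 1007 and 1400 FPKM in the authors' deposited table (q = 0.499).

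The largest rises among genes with at least 5 FPKM in the authors' deposited table were those of CYP82G1 (11.8-fold), AT2G43580 (11.1-fold), DXPS1 (10.7-fold), AT5G39090 (10.6-fold) and ELI3-2 (10.2-fold). The largest falls there were SAUR15 (21.5-fold), DDF1 (19.2-fold), AT1G29450 (17.8-fold), IAA29 (17.4-fold) and BBX16 (16.5-fold). In that deposited table AT1G03020, AT1G53690, AT2G37030, AT3G25880 and AT3G60650 were listed at 0 in ago1-36, and AT1G32680 and AT3G47347 at 0 in WT.

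**Figure D3:**
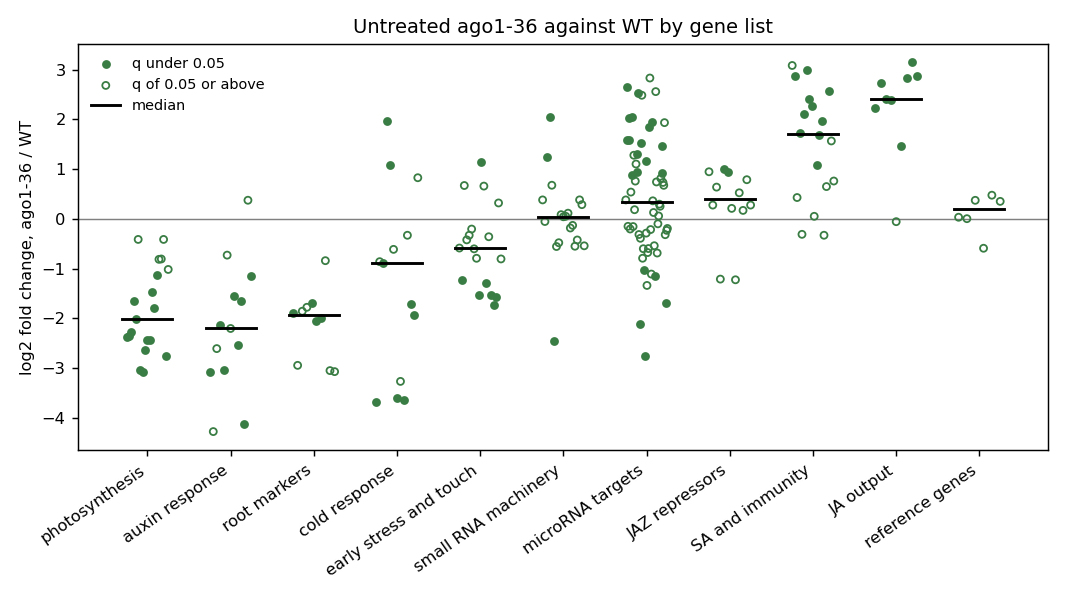
Each point is a tested member of a gene list, placed on the vertical axis by its log2 fold change of untreated ago1-36 over untreated WT in the authors' deposited table; filled points have a q under 0.05 and black bars are medians. Photosynthesis genes have a median of -2.02 and JA output genes one of 2.42.

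Genes that respond to MeJA in WT were set against genes that differ in untreated ago1-36, whose libraries are separate. Of 18702 genes tested in both tables, 207 rose with MeJA and were higher in ago1-36, where independent lists would share 59.9 (two-sided Fisher's exact test, adjusted p = 2.39e-59), and 106 fell with MeJA and were lower in ago1-36, against 24.7 (odds ratio 6.00, adjusted p = 3.82e-39). Opposite pairs also exceeded independence. A rise with MeJA and a lower level in ago1-36 were shared by 108 genes, against 65.8 (Fisher's exact test, odds ratio 1.79, adjusted p = 2.64e-07), and a fall with a higher level by 52, against 22.5 (odds ratio 2.60, adjusted p = 1.99e-08).

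The small RNA libraries were compared for the kind of RNA held by nuclear AGO1. Reads of 21 nt, the usual length of plant microRNAs, made up 72.5% and 59.2% of the untreated WT libraries, 43.5% of WT with buffer, 33.7% of WT with MeJA and 38.4% of coi1 with MeJA. A T as the leading base, the form AGO1 prefers, was found in 95.7% and 89.0% of reads in untreated WT, and in 62.5%, 52.3% and 59.7% in the other libraries in that order. Reads of 19 nt made up 0.923% and 1.66% of the untreated libraries, 3.64% with buffer, and 14.8% and 14.2% with MeJA in WT and coi1. The exact Clopper-Pearson 95% interval for the 19-nt share with buffer was 3.63% to 3.65%, and all intervals here cover counting error only, because PCR reads without molecular identifiers are not independent molecules. With 1 library per MeJA group these differences have no replicate check.

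**Figure D4:**
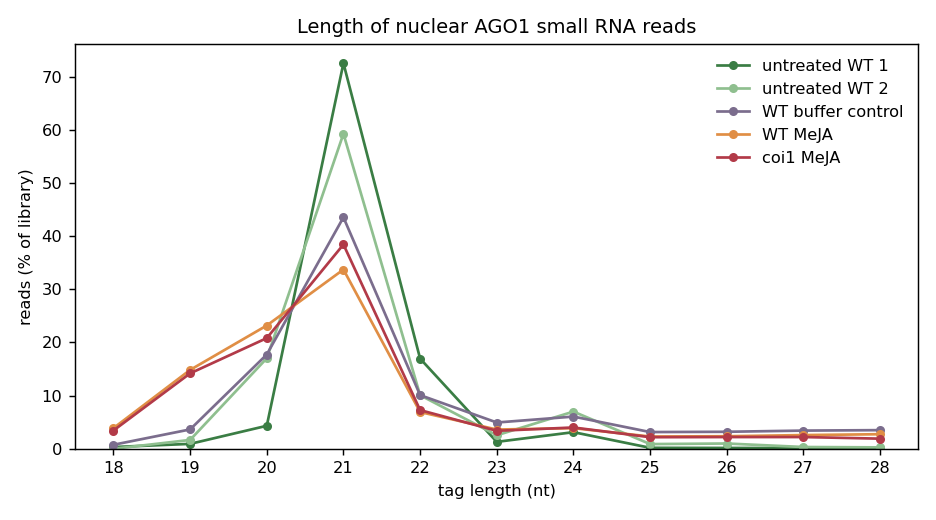
The horizontal axis is the tag length in nt and the vertical axis the percentage of a library's reads of that length, with 1 line per nuclear AGO1 library. The 21-nt peak reaches 72.5% in untreated WT 1 and 33.7% in WT with MeJA, and the MeJA libraries hold 14.8% and 14.2% at 19 nt.

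Known microRNA sequences made up much of the untreated libraries. The 50 mature sequences looked up accounted for 70.9% and 53.4% of reads in untreated WT, 22.2% in WT with buffer, 19.7% in WT with MeJA and 24.6% in coi1 with MeJA. By mean RPM (read counts scaled to the same library total) over the 4 WT libraries, the leading families were miR159, miR167, miR158, miR166, miR396, miR161, miR162, miR165, miR398 and miR157. This order depends on single libraries: miR157, for example, was at 11885 RPM in untreated WT 1 and at 837, 175 and 124 in the other WT libraries. The miR159a sequence TTTGGATTGAAGGGAGCTCTA and its relative miR159b, which act on MYB factors, summed to 174824 and 117139 RPM in untreated WT, 58575 with buffer and 36518 with MeJA. The untreated libraries differed widely from each other. The miR167 family, which targets auxin response factors, was at 371755 RPM in untreated WT 1 and 1629 in untreated WT 2, and miR166 (TCGGACCAGGCTTCATTCCCC) at 5606 and 87924.

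MicroRNA families were compared between MeJA and buffer in WT over 32 families with at least 100 reads in 1 of the libraries. Their median log2 ratio was -0.45, and 26 of the 32 were lower with MeJA. Both values depend on the scaling of the libraries: with median-of-ratios scaling the median was 0.22, with 22 families higher and 10 lower. The largest ratio was that of miR394 (TTGGCATTCTGTCCACCTCC), at 8.26 RPM with buffer and 63.2 with MeJA (ratio 7.65, exact conditional binomial 95% interval 6.36 to 9.27), followed by miR158 (ratio 1.75), miR165 (1.32) and miR319 (1.28). The lowest ratios were those of miR824 (0.326, interval 0.255 to 0.413), miR823 (0.392), miR168, which targets AGO1 (0.397), and miR390 (0.450). Log2 ratios between the 2 untreated WT libraries had an SD of 4.31 over 36 families. Each family was set against its own ratio there, which is 1 difference and gives no spread. With scaling to total reads, 3 of 31 families (miR159, miR163 and miR399) differed more in size between MeJA and buffer than between those libraries. With median-of-ratios scaling their log2 ratios were -0.01, 0.08 and 0.17, smaller in size than that difference, while miR156 (0.75) and miR319 (1.03) exceeded theirs. Which families exceed their own difference thus depends on the scaling. Of the 8 ratios named above, all but that of miR319 were smaller in size than the family's difference between the untreated libraries with both scalings. Among them is miR394, which was at 0.532 and 1761 RPM in the untreated libraries.

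Under MeJA, coi1 and WT were closer to each other. Over 31 families the median log2 ratio of coi1 to WT was 0.16, with 19 higher and 12 lower. The largest ratios were those of miR173, the trigger of TAS1 and TAS2 siRNAs (TTCGCTTGCAGAGAGAAATCAC, 1.63, interval 1.45 to 1.83), miR824 (1.54), miR403 (1.40) and miR162 (1.38), and the smallest those of miR395 (0.434, interval 0.341 to 0.549), miR827 (0.677), miR399 (0.773) and miR408 (0.803). With scaling to total reads, of 30 families with a ratio between the untreated WT libraries, 2 (miR395 and miR399) differed more between coi1 and WT than between those replicates. The other ratios named here were smaller in size than the same family's difference between the untreated libraries. The TAS1 siRNA TTCTAAGTCCAACATAGCGTA was at 16434 and 477 RPM in untreated WT, 39.6 with buffer, 24.7 with MeJA and 24.5 in coi1 with MeJA. The TAS3 sequences summed to 375, 1111, 96.8, 138 and 173 RPM in the same order.

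**Figure D5:**
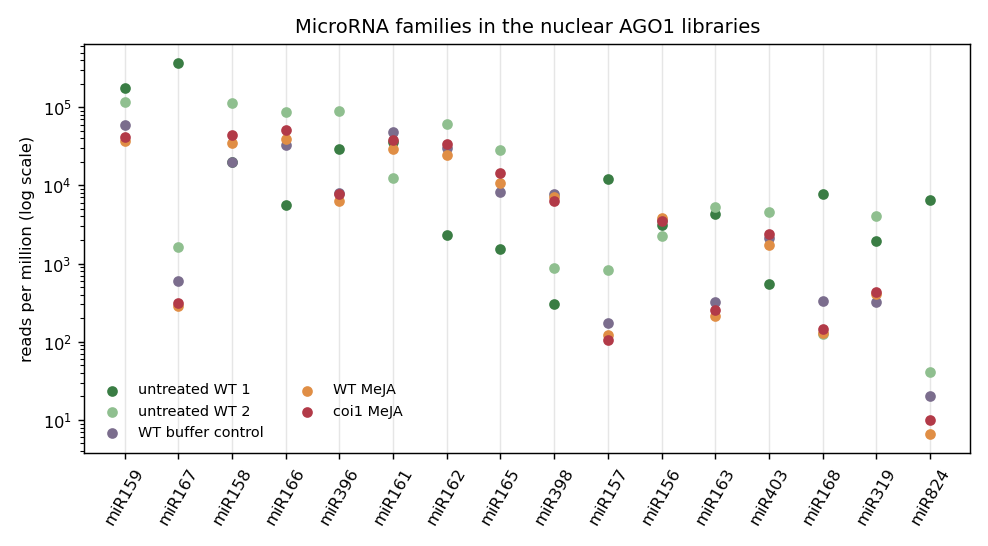
RPM on a log axis for the 16 microRNA families with the highest mean over the 4 WT libraries, with 1 point per nuclear AGO1 library. The miR167 points of the untreated libraries lie at 371755 and 1629 RPM, and those of the MeJA experiment between 284 and 594.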

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

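All alternatives here were planned except counting the shortened form with the mature sequence, which was chosen after the data were seen. No paired analysis was possible because the RNA-seq tables hold 1 pooled value per group and the columns carry no replicate numbers, and for the same reason no replicate could be left out. The filter on low values could not be removed, since genes without the test status OK have no test. Alternatives that need a genome (only reads with 1 site, structural RNA left out) were not run. With an FPKM minimum of 1 the counts hardly moved, as in WT with MeJA with 1502 calls. At a q under 0.01 the genes that fell with MeJA numbered 203 in WT and 216 in ago1-36, and untreated ago1-36 had 1543 calls, 804 higher and 739 lower; with a 2-fold minimum as well as the threshold, 213 fell with MeJA in WT, and ago1-36 had 670 calls, 537 higher and 133 lower. These counts are lower by construction. A pseudocount cannot turn the sign of a fold change and lowers its size most in genes near 0: with a pseudocount of 1 the log2 fold change of TPS04 in WT fell from 6.66 to 4.35. Median-of-ratios scaling shifted all genes alike, by at most 0.0141 on the log2 scale. Of the 238 named gene values, 30 lost their call at a q of 0.01. Of 29 list results, 28 stayed on their side of the threshold with a background of at least 5 FPKM, and the seed storage list in untreated ago1-36 passed there (2 of 2 lower, adjusted p = 0.0170, Fisher's exact test). The overlaps kept their direction and their calls.

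The smaller response of raised genes in ago1-36 kept its sign under each planned choice of genes, but these choices share 873 genes and its size varied. The median difference was -0.46 over genes called in WT, -0.44 in both, -0.38 in either and -0.32 in ago1-36. For this last choice it was -0.26 on the log2(value + 1) scale. For genes that fell, the median difference turned to -0.0354 over genes called in ago1-36, and was 0.14 over genes called in either and 0.16 over genes called in both; choosing genes by their call in WT favours large WT values. The median microRNA ratio of MeJA to buffer was -0.29 scaled to the reads of 20 to 22 nt, -0.40 with a minimum of 20 reads, and turned to 0.22 with median-of-ratios scaling over all 5 libraries. That scaling and the one to reads of 20 to 22 nt shift every family alike by construction, so they move the median without bearing on differences among families. The widely differing untreated libraries enter the median-of-ratios factors, which may therefore be unstable, though this was not tested. The median microRNA ratio of coi1 to WT was 0.10 scaled to the reads of 20 to 22 nt and 0.10 with median-of-ratios scaling. As shares of the reads of 20 to 22 nt, 21-nt reads made up 77.3% and 68.6% in untreated WT, 61.0% with buffer, 52.8% with MeJA and 57.8% in coi1 with MeJA. Depth limits the rarer families, such as miR172, whose ratio of MeJA to buffer of 0.899 has an interval from 0.490 to 1.63.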

Other observations

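Genes were grouped by the letters of their symbol after the data were seen, so a group can hold unrelated genes that share a symbol. Of 126 such groups with at least 10 tested genes in WT with MeJA, the tau-class glutathione transferases rose in 11 of 25 members (two-sided Fisher's exact test, adjusted p = 1.78e-06), GSTU26 from 16.2 to 211 FPKM and GSTU6 from 24.2 to 269 in the authors' deposited table. Genes with the symbol CYP, mostly cytochromes P450, rose in 35 of 141 members (adjusted p = 1.02e-11, exact test) and fell in 14 (7.25e-05), and glycosyltransferases of the UGT family rose in 14 of 51 (2.00e-05). MAPKKK genes, kinases at the head of signalling cascades, rose in 5 of 13 (0.00601), among them MAPKKK17 from 2.07 to 20.3 FPKM in that deposited table. Genes with the symbol CRK, mostly cysteine-rich receptor-like kinases, fell in 8 of 28 members (7.50e-06, exact test), including CRK2 from 12.0 to 4.92 FPKM, and expansins fell in 5 of 16 (0.000518).

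In untreated ago1-36 the receptor-like proteins were higher in 21 of 45 members (adjusted p = 5.02e-12, Fisher's exact test), RLP40 from 5.33 to 32.5 FPKM in the authors' deposited table, and WRKY factors in 14 of 53 (6.78e-05). Multidrug-resistance transporters of the ABCC type were higher in 8 of 15 (2.62e-05, exact test). Families with more lowered members than the background included fasciclin-like arabinogalactan proteins in 9 of 14 members (3.59e-06, exact test), FLA9 from 466 to 105 FPKM in that deposited table, very-long-chain fatty acid elongases of the KCS family in 9 of 17 (1.63e-05), and SAUR genes, rapid auxin responders, in 8 of 16 (6.11e-05). Genes with the symbol SPL, many of them targets of miR156, were higher in 5 of 16 (0.0242, exact test), SPL10 from 8.64 to 35.2 FPKM in the authors' deposited table.

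All tests of explanations in this section were chosen after the patterns were seen. The smaller MeJA response of raised genes in ago1-36 is a hypothesis about the mutant. If it came from choosing genes by their WT call, genes chosen in ago1-36 would show no deficit, but their median difference was -0.32. Of these 1117 genes, however, 873 also rose in WT, so this choice cannot exclude an effect of the WT call. Below 0 were 843 of 1113 genes raised in ago1-36 and 771 of 872 raised in both. Genes raised in ago1-36 alone therefore mostly lay above 0, a choice that in turn favours large ago1-36 values. The median over all genes was -0.0145, but each table was normalized within itself, which holds this median near 0. It therefore cannot test for a difference in scaling. A scaling shift moves all genes alike, so by itself it would not set the raised genes apart from the others. A handling or stress response already on in the ago1-36 buffer plants remains a candidate explanation: over genes raised in both genotypes the excess of ago1-36 over WT was larger by 0.33 (log2) among buffer controls than among untreated plants, and early stress and touch genes were higher in 18 of 18 members there against 4 of 18. The buffer values also enter the MeJA fold changes and the choice of genes. A higher buffer level thus partly restates the smaller response and is no separate test of handling. JA output genes went the other way, at 0.44 among buffer controls and 2.42 among untreated plants. Photosynthesis genes, none of which passed with MeJA, also differed between these tables, at -0.64 among buffer controls and -2.01 among untreated plants. These contrasts therefore do not decide for or against handling. Whether the mutant, the handling of the plants or the library kit, which the labels do not assign to samples, set the higher starting level stays open, since genotype and table go together.

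Reads of 19 nt made up 14.8% of the WT library with MeJA and 3.64% with buffer; the coi1 library with MeJA held 14.2%, but with 1 such library and no coi1 library with buffer this excludes neither an effect through COI1 nor one that bypasses it. ACGTGACGAGATTTCTCTC alone gave 45.8% of the 19-nt reads with MeJA in WT (67984 RPM against 2451 with buffer), and without the 10 most abundant 19-nt tags of each library the shares fell to 2.81% with MeJA and 1.33% with buffer, so a few sequences carried most of the rise; the remaining ratio of 2.11 is little above that between the untreated WT libraries (1.04% and 0.533%). Shorter size selection or trimming predicted a higher share of the form lacking the last base in nearly all abundant tags, and 64.0% of 300 tags showed it, between the bounds of 60% and 80% written before this share was computed but after single shortened tags had been seen. Values on either side of trimming include the 20-nt form ACGTGACGAGATTTCTCTCC, which was also more frequent with MeJA (25755 against 7167 RPM), and the median share of short forms, at 9.79% with MeJA and 7.35% with buffer but 24.6% and 19.4% in untreated WT, whose libraries have the fewest 19-nt reads. The tags were chosen by their reads in the libraries of the MeJA experiment, and some had few or no reads in untreated WT, where such shares are unreliable. Over the 12 tags with a name here, the medians were 6.22% with MeJA, 4.69% with buffer, and 1.26% and 7.67% in untreated WT. As causes of the rise in 19-nt reads, trimming and an effect of MeJA, through COI1 or not, cannot be told apart with 1 library each.

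MicroRNA levels differed between the untreated WT libraries far beyond counting error: over the 22 families with at least 1000 reads in both, the median absolute log2 ratio was 1.57. If reads taken by the dominant miR167 family had displaced the rest, the other families would share a ratio, but the SD of their log2 ratios was 2.46. No biological explanation was tested, because both libraries carry the same group label. Untreated WT 2 held no reads of 18 nt, and no miR158a reads lacking the last base beside 756201 full ones. In untreated WT 1 there were 49635 reads of 18 nt and 1.86 shortened miR158a reads per 100 full ones. Whether the 2 libraries were processed alike was not tested.

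Several abundant tags with no name here were far more frequent in the libraries of the MeJA experiment than in those of untreated WT. TCGGTGGATCTTAGAAAATTA was at 82111, 56457 and 57907 RPM in WT with buffer, WT with MeJA and coi1 with MeJA, and at 5104 and 0 in untreated WT. ATGGGAGCGGTGATTCAGGC was at 65454, 69565 and 46778 RPM in the same libraries, and at 216 and 4.79 in untreated WT.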
